A study of Mus musculus with 6 samples.

How the data were processed

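RNA from mouse bone marrow cells depleted of mature blood lineages was measured on 6 Affymetrix mouse genome expression arrays, 1 colour and 1 sample per array. Per the labels, 3 arrays held C57B/L6 samples and 3 held B.D(Chr5) samples, all from adult female mice of 6 to 16 weeks, and the 3 samples of a strain were biological replicates. The labels do not say whether each replicate was 1 mouse or a pool, so p-values measure the spread between these samples. The deposited values are probe set intensity on a linear scale, made with MAS5 per the submitters' processing notes; the MAS5 version and settings are not given in the sources used here. The values show that each array had been scaled to a mean of 500 after trimming 2% at each end. No array duplicated another, with 0 pairs of arrays holding identical values.

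The table held 45101 probe sets, of which 64 controls were left out. In the platform annotation, 34945 of the remaining probe sets had 1 gene symbol, 932 had several and 9160 had none. Symbols were updated through Entrez gene identifiers to the RefSeq annotation of GRCm38.p6, which held 34741 of the probe sets with 1 symbol and gave a chromosome for 34735. No genome build comes with the arrays' values, so chromosomes and the order of genes were taken from that annotation and no coordinates are given. Probe sets with several genes or none were counted and not named.

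Intensities were turned into log2(signal + 16), and only the upper 50% of probe sets by mean over the 6 arrays were tested. Fold changes are therefore on that scale and understate changes of dim probe sets. The strains were compared in limma 3.58.1 (R 4.3.3) with lmFit and eBayes with trend, strain being the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All limma and camera tests were two-sided. A gene counted as called if any of its tested probe sets passed. The 95th percentile of 27 bacterial control probe sets on each array was taken as its background level. Where all 3 arrays of the dimmer strain lay at or below that of their own array, the fold change is given as a bound. The bound was computed from the mean log2 signal of the brighter strain against those percentiles. No detection calls were used. The number of arrays, 3 per strain, limits the precision. In data simulated for this comparison over 22518 probe sets, 20 of 67 changes of 0.5 on the log2 scale, 59 of 67 changes of 1 and 66 of 66 changes of 2 were recovered. The 155 calls also held 3 of 38 probe sets of a simulated list shifted by 0.3, and 7 false calls. The simulated noise was normal and independent between probe sets, with no outlying array. The simulation also gave more calls than the real comparison, 155 against 41, which makes the adjusted threshold easier to pass. These counts need not hold for the real arrays, where recovery may be lower.

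The share of called genes on a chromosome was compared with that of all other tested genes by a two-sided Fisher exact test. The run test took the shortest stretch of tested genes that held 80% of a chromosome's called genes and set it against 10000 random placements of as many calls, one-sided for a shorter stretch. Both were fixed for chromosome 5 before the data were examined, and those for other chromosomes were added after the results were seen. Gene lists fixed before the data were examined (21 lists, 20 of them tested) covered 11 cell types that the cell preparation could hold and 9 groups of processes or chromosome 5 genes; the remaining list held 6 background check genes and was only described. They were tested with camera on the brightest probe set of each gene, with a preset correlation of 0.01 and, as an alternative, an estimated correlation.

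Genes were named by a rule fixed before the data were examined: the 12 called genes with the largest log2 change in each direction, up to 8 called genes on chromosome 5, every called member of a list or otherwise its 2 members of smallest p, and always Kit and Flt3. Alternatives covered pseudocounts of 1 and 64, the filter on dim probe sets, quantile normalization and centring on the median, eBayes without trend, the replicate number as a block, leaving out probe sets whose names end in _x_at, a minimum change of 1.5-fold, an unadjusted p of 0.01 for the chromosome tests, camera with an estimated correlation, the mean over a gene's probe sets, lists without chromosome 5 genes, and leaving out each array in turn. Leaving out the array with the highest 18S signal of each strain was added after the data were seen.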

Results

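Expression was compared between 2 mouse strains, C57B/L6 and B.D(Chr5), in bone marrow cells from which mature lineages had been removed to enrich for haematopoietic stem and progenitor cells. The label of the second strain names chromosome 5. Each strain had 3 arrays. The median signal of an array lay between 65.1 and 79.5, and the 95th percentile of the bacterial controls lay between 21.8 and 38.0. Pearson's r across the tested probe sets, which are not independent replicates, lay between 0.985 and 0.986 for pairs of C57B/L6 arrays, between 0.977 and 0.986 for pairs of B.D(Chr5) arrays and between 0.974 and 0.987 for pairs across the strains. The share of probe sets above the bacterial controls was 70.4% ± 0.984 (SD, n = 3) in C57B/L6 and 65.6% ± 2.86 (SD, n = 3) in B.D(Chr5), with a two-sided exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. The signal of the 18S ribosomal RNA probe set, which reads residual ribosomal RNA, ranged from 1726 to 20010.3 over the arrays and averaged 7273 ± 5368 in C57B/L6 and 11430.1 ± 9194 in B.D(Chr5) (SD, n = 3 each; exact permutation p = 0.7). The 3' to 5' ratio of actin was 1.20 ± 0.010 and 1.18 ± 0.037 (SD, n = 3 each; exact permutation p = 0.6), and that of Gapdh was 0.793 ± 0.046 and 0.825 ± 0.032 (SD, n = 3 each; exact permutation p = 0.5).

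The first question was which transcripts differed between the strains. The 2 largest differences among the named genes were those of Ifi202b and Mndal. Both belong to the p200 family of interferon-inducible genes on chromosome 1, whose products include sensors of cytosolic DNA. Ifi202b lay at the level of the bacterial controls in C57B/L6, with a signal of 3.12 ± 1.22, and reached 4377 ± 762 in B.D(Chr5) (SD, n = 3 each), at least 111-fold higher. Mndal went the other way, from 4717 ± 832 in C57B/L6 to the control level of 2.58 ± 2.07 in B.D(Chr5) (SD, n = 3 each), at least 100.3-fold lower. Ifi209, of the same family, fell by 3.70 on the log2 scale, from 2930.0 ± 283 to 213 ± 42.5 (SD, n = 3 each). Members of this family resemble each other closely, so the assignment of a probe set to a single member is uncertain, and the other probe set of Ifi209 differed by 0.14 in the same direction on the log2 scale. In the same part of chromosome 1, Slamf1, which encodes the stem cell marker CD150, was higher in B.D(Chr5), at 696 ± 128 against 304 ± 52.8 in C57B/L6 (SD, n = 3 each). Its log2 change was 1.15 with an SE of 0.17 (limma adjusted p = 0.0361), and it kept the call in 1 of the 6 fits with an array left out. Cd84, another SLAM family receptor, fell by 1.07 on the log2 scale, and Pex19, which brings membrane proteins to peroxisomes, fell by 1.47. Of the tested probe sets, 1 of 2 passed for Slamf1, 1 of 1 for Cd84 and 1 of 3 for Pex19, and the others went the same way.

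On chromosome 3, 7 named genes were lower and 3 were higher in B.D(Chr5). Cnn3, encoding the actin-binding protein calponin 3, fell from 4819 ± 343 to 1579 ± 214 (SD, n = 3 each), a log2 change of -1.61 with an SE of 0.11 (limma adjusted p = 1.86e-04). All 6 of its tested probe sets were lower and 4 of them passed the threshold. Mettl14, a subunit of the enzyme that writes N6-methyladenosine into RNA, fell from 936 ± 111 to 203 ± 47.5 (SD, n = 3 each), a log2 change of -2.14 with an SE of 0.18 (limma adjusted p = 6.95e-04). Tlcd4, for which 1 of 2 probe sets passed, had a log2 change of -2.37. Alg14, which acts in protein N-glycosylation, fell by 1.77 on the log2 scale, with B.D(Chr5) signals of 32.7, 40.5 and 21.0, the last below the 95th percentile of the bacterial controls of its array, so the size of this change is uncertain. Its other, brighter probe set had a log2 change of -0.10 and did not pass. Fnbp1l, a regulator of actin assembly at curved membranes, fell by 1.61, and Sec24d, a coat protein of vesicles leaving the endoplasmic reticulum, fell by 1.32. Chil3, a chitinase-like protein of myeloid cells with a near-identical relative, fell from 2772 ± 293 to 981 ± 287 (SD, n = 3 each). Of the 3 higher genes, Fam102b had signals of 1617 ± 147 in C57B/L6 and 3503 ± 223 in B.D(Chr5) (SD, n = 3 each). The others were Rwdd3, with a log2 change of 1.02, and the zinc transporter gene Slc30a7, with a log2 change of 0.77. The other probe set of Slc30a7 went the opposite way, and those of Rwdd3 and Alg14 differed by 0.16 and 0.10 in the called direction.

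Chromosome 5 held 4 called genes. AI506816 rose from 38.2 ± 5.39 in C57B/L6 to 1912 ± 359 in B.D(Chr5) (SD, n = 3 each), a log2 change of 5.14 with an SE of 0.17 (limma adjusted p = 3.66e-07). Lcorl rose from 101 ± 12.9 to 422 ± 62.9 (SD, n = 3 each), a log2 change of 1.90 with an SE of 0.17 (limma adjusted p = 0.00129). For Lcorl 1 of 4 tested probe sets passed, and the other 3 had log2 changes of 0.58, 0.10 and 0.057. Pus7, which encodes a pseudouridine synthase, rose by 0.86, and Dnajc2, a ribosome-associated chaperone gene, fell by 1.35, both on the log2 scale. For Dnajc2 1 of 3 tested probe sets passed, and the brighter others had log2 changes of -0.071 and -0.059. AI506816 and Pus7 had 1 tested probe set each. Whether strain variants in the sequence under the probes account for the values of these 4 genes was not tested. The receptor genes Kit and Flt3, both on chromosome 5 and central to early haematopoiesis, did not pass the threshold. Kit had a signal of 4925 ± 643 in C57B/L6 and 4559 ± 860.2 in B.D(Chr5) (SD, n = 3 each), a log2 change of -0.12 with an SE of 0.14 (limma adjusted p = 1.00). For Flt3 the signals were 2780 ± 402 and 2271 ± 350 (SD, n = 3 each), a log2 change of -0.29 with an SE of 0.13.

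The other 4 named genes were all higher in B.D(Chr5). The immunoglobulin light chain variable gene Iglv1 had signals of 2270 ± 268 in C57B/L6 and 7818 ± 1088 in B.D(Chr5) (SD, n = 3 each) on the 1 of 3 tested probe sets that passed, the others having log2 changes of 0.56 and 0.24. Igkv9-120, another such gene, had a log2 change of 1.79, and both its tested probe sets passed. The scavenger receptor gene Cd163l1 had a log2 change of 1.46 on its 1 tested probe set, whose name ends in _x_at. Its signals were 41.3 ± 7.31 in C57B/L6 and 142 ± 16.7 in B.D(Chr5) (SD, n = 3 each), and it lost the call whichever array was left out. For the pseudogene Pisd-ps3, which had no chromosome in the annotation, 3 of 5 tested probe sets passed. Variable genes are near-identical to their relatives, so the assignment to a single gene is uncertain.

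Of 22518 probe sets tested, 41 passed the threshold in limma, 22 higher and 19 lower in B.D(Chr5). All 41 changed at least 1.5-fold, and in all 41 the 3 arrays of one strain lay above the 3 of the other, a separation found in 9.40% of all tested probe sets against 10% by chance. They comprised 32 probe sets of 24 named genes, 5 with several symbols and 4 with none. The count of probe sets at an unadjusted p under 0.05 was 1069, against 1126 in the absence of any difference. Leaving out B.D(Chr5) replicate 2 raised the count of calls to 73, and leaving out B.D(Chr5) replicate 1, C57B/L6 replicate 2 or C57B/L6 replicate 3 lowered it to 21, 24 and 23. Of the 24 named genes, 13 lost the call when at least 1 of the arrays was left out, and 11 passed in every setting in which they were tested: AI506816, Cnn3, Fam102b, Fnbp1l, Ifi202b, Ifi209, Iglv1, Lcorl, Mettl14, Mndal and Tlcd4. Cd84, Rwdd3, Slc30a7 and Cd163l1 lost the call whichever array was left out. Slamf1 and Dnajc2 each kept it in 1 of the 6 fits with an array left out.

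**Figure D1:**
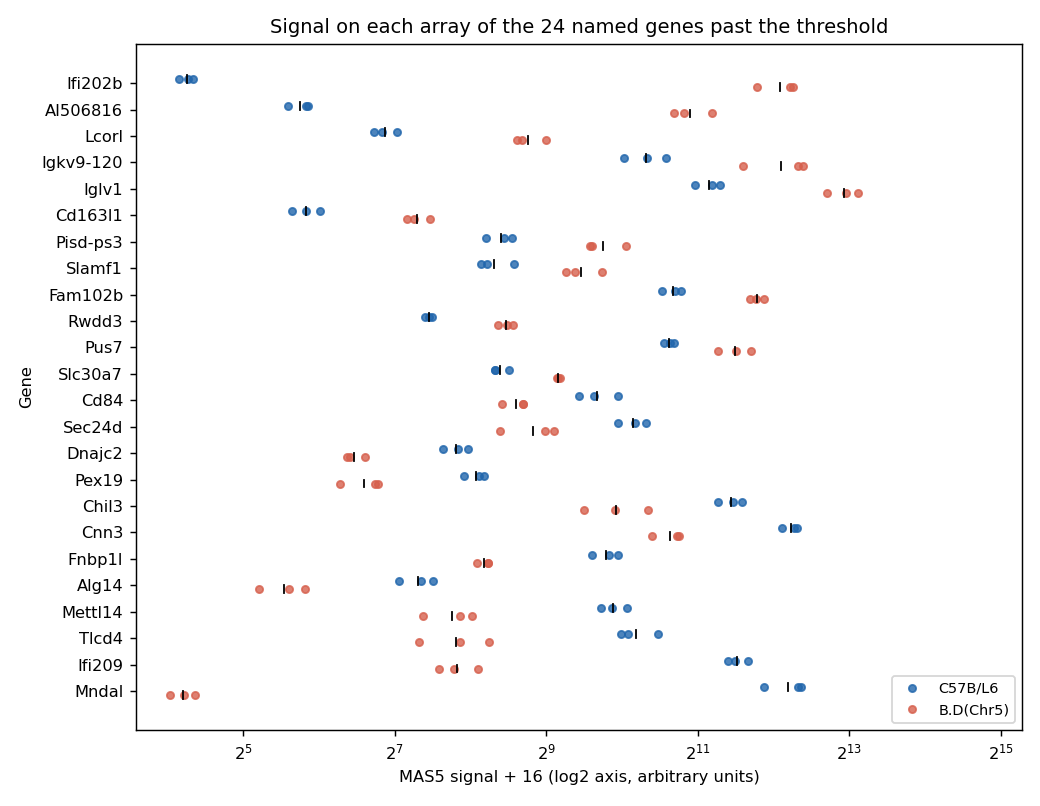
Signal on each array of the 24 named genes past the threshold, on a log axis of signal + 16, with 3 points for C57B/L6 and 3 for B.D(Chr5) in each gene and a tick at each mean. The points of the strains do not overlap for any of the 24 genes, and the widest gaps are those of Ifi202b and Mndal.

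The second question was whether the called genes lay on chromosome 5, for which the strain is named. They lay mostly on chromosomes 3, 1 and 5, which together held 20 of the 23 called genes with a known chromosome (87.0%) and 16.9% of the tested genes. Chromosome 5 held 4 of the 23 called genes (17.4%) against 6.53% of the tested genes, a difference that did not pass the threshold (odds ratio 3.02, two-sided Fisher exact p = 0.0593, adjusted over the chromosomes 0.395). Chromosome 5 held 8 of 54 called genes without B.D(Chr5) replicate 2 (Fisher exact p = 0.0230), and 24 of 203 genes at an unadjusted p under 0.01 (Fisher exact p = 0.00568). Chromosome 3 held 10 of the 23 (odds ratio 15.6, Fisher exact p = 3.81e-08, adjusted 7.63e-07). Chromosome 1 held 6 (odds ratio 5.97, Fisher exact p = 0.00137, adjusted 0.0137). These chromosomes were singled out after the results were seen. Without B.D(Chr5) replicate 2 the Fisher exact p for chromosome 1 was 0.229, and without C57B/L6 replicate 1 it was 0.0575.

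The called genes also lay close together along these chromosomes. On chromosome 5, all 4 lay within 138 consecutive tested genes, from Dnajc2 to Lcorl, where random placements of the calls had a median of 430 (one-sided permutation p = 0.027). On chromosome 3, 8 of the 10 lay within 26 tested genes, from Slc30a7 to Mettl14, against a median of 288 for random placements. On chromosome 1, 5 of the 6 lay within 21 tested genes, from Slamf1 to Mndal, against a median of 300. For both, the one-sided permutation p was 1e-04, the smallest that 10000 placements can give. Without any 1 of the C57B/L6 arrays or B.D(Chr5) replicate 1, only 3 genes were still called on chromosome 1. They were Ifi209, Mndal and Ifi202b, similar genes of 1 family within 5 tested genes, which the placements treat as independent calls. Without B.D(Chr5) replicate 2 or 3, 5 genes were called there, 4 of them within 17 tested genes from Pex19 to Ifi202b (permutation p = 2e-04). The chromosome 5 stretch rested on 4 genes and was not past the threshold whichever array was left out. In 4 of these 6 settings only AI506816 and Lcorl were still called on the chromosome, so the stretch stayed about as long while fewer calls were placed. It spanned 131 genes without C57B/L6 replicate 1 (permutation p = 0.333), 293 without B.D(Chr5) replicate 2 (permutation p = 0.103) and 131 to 133 without one of the others, where permutation p values ran from 0.0931 to 0.346. Of the 24 chromosome 5 genes at an unadjusted p under 0.01, 20 lay within 255 tested genes (permutation p = 1e-04).

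**Figure D2:**
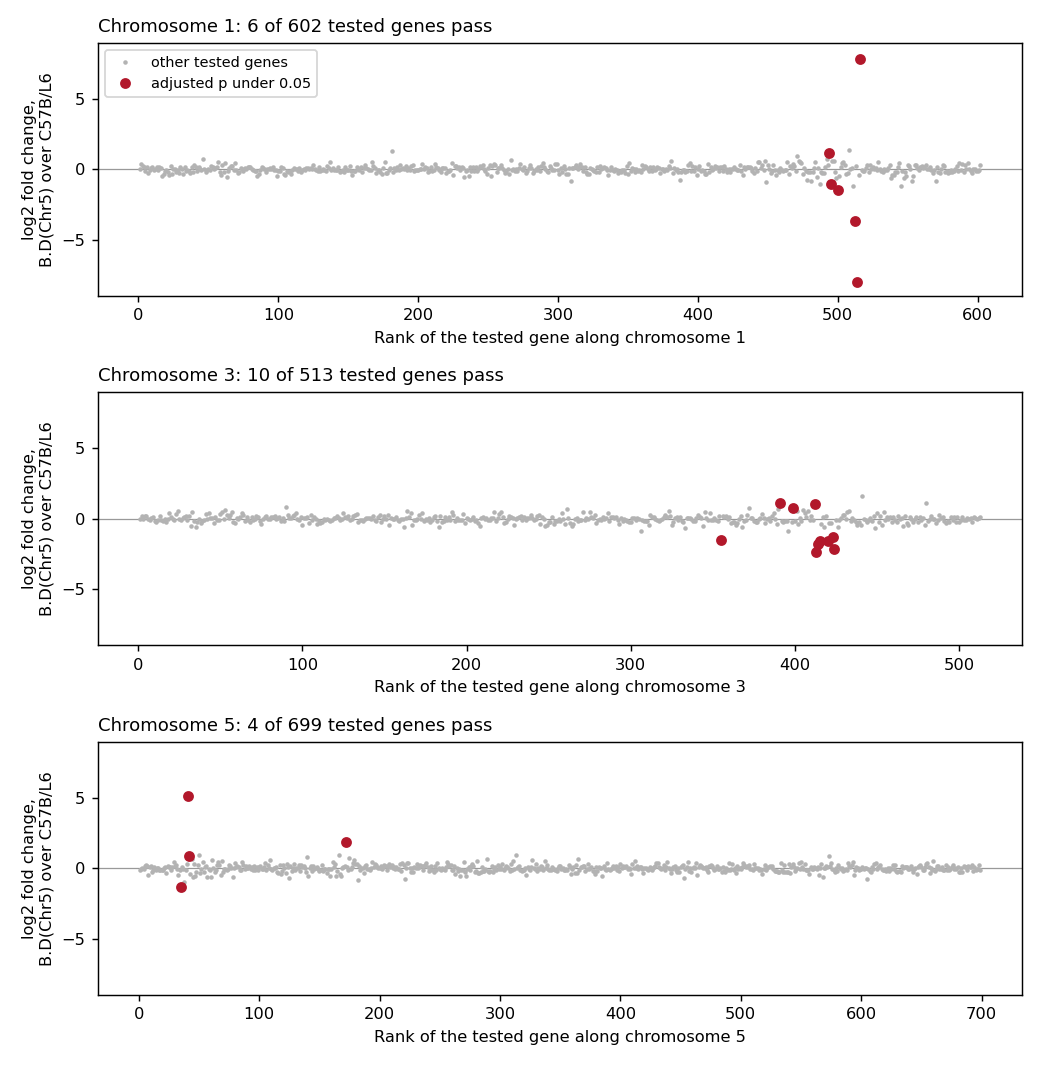
Log2 fold change of B.D(Chr5) over C57B/L6 against the order of tested genes along chromosomes 1, 3 and 5, each point being 1 gene and called genes marked. The 6 called genes of chromosome 1 and 8 of the 10 of chromosome 3 sit in short stretches. On chromosome 5, 3 of the 4 (ranks 35, 41 and 42) lie close together and Lcorl (rank 172) lies apart.

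The third question was which blood cell types and processes moved with the strain, taken from the fixed lists. The lists of granulocyte-monocyte progenitors, of mast cells, basophils and eosinophils, and of maturing neutrophils were higher in B.D(Chr5) as groups with the preset correlation and not with an estimated one. All 10 measured genes of granulocyte-monocyte progenitors had positive log2 changes, with a median of 0.42. Among them the granule protease gene Ctsg had signals of 9643 ± 642 in C57B/L6 and 14415 ± 2914 in B.D(Chr5), and Prtn3 had 10812 ± 914 and 14845 ± 2131 (SD, n = 3 each). The list passed camera with the preset correlation (adjusted p = 1.14e-09; adjusted p = 0.440 with an estimated correlation). Of its genes, 0 passed limma over all genes tested and 5 passed adjusted over the list alone. Of 9 measured genes of mast cells, basophils and eosinophils, 8 were positive and Gzmb, at -0.45, was negative. The median was 0.96, and was 0.62 without B.D(Chr5) replicate 1 and 0.58 without B.D(Chr5) replicate 3. The IgE receptor subunit gene Fcer1a had a log2 change of 1.38 and the eosinophil granule protein gene Prg2 had 0.96. That list also passed (adjusted p = 9.07e-07; adjusted p = 0.440 with an estimated correlation), with 0 genes over all genes tested and 3 adjusted over the list alone. Of 12 genes of maturing neutrophils, 9 were positive, with a median of 0.38 (camera adjusted p = 6.84e-05; adjusted p = 0.549 with an estimated correlation), which was 0.19 without B.D(Chr5) replicate 3. Chil3 was the 1 called member and was lower, while adjusted over the list alone 6 passed, 5 of them higher.

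Lists of other cell types had medians in both directions, and 0 passed with an estimated correlation. Genes of stroma, bone and endothelium were higher in B.D(Chr5) for 9 of 10 genes, with a median of 0.96 (camera adjusted p = 1.33e-06; adjusted p = 0.440 with an estimated correlation). Of these, 0 were called over all genes tested and 1, Lpl, adjusted over the list alone. The median was 0.49 without C57B/L6 replicate 2 and 0.63 without B.D(Chr5) replicate 2. The niche chemokine gene Cxcl12 had a log2 change of 0.97. Of 8 plasma cell genes, 7 were positive, with a median of 0.25 (camera adjusted p = 1.96e-04; adjusted p = 0.292 with an estimated correlation). Adjusted over the list alone 3 passed, against 0 over all genes tested. The median was 0.11 without B.D(Chr5) replicate 2. Mzb1 had signals of 704 ± 17.8 in C57B/L6 and 1135 ± 215 in B.D(Chr5) (SD, n = 3 each), and the secretory cell regulator gene Xbp1 had a log2 change of 0.35. B lymphoid genes were positive for 11 of 14, with a median of 0.34 (camera adjusted p = 0.00405; adjusted p = 0.569 with an estimated correlation). The surrogate light chain genes Igll1 and Vpreb1 had log2 changes of 0.83 and 0.82. Monocyte and dendritic cell genes were positive for 11 of 14, with a median of 0.16 (camera adjusted p = 0.0315; adjusted p = 0.651 with an estimated correlation). The B lymphoid median was 0.011 without B.D(Chr5) replicate 3, and the monocyte and dendritic cell median was -0.014 without C57B/L6 replicate 1. In these 2 lists, 0 genes passed over all genes tested and 0 adjusted over the list alone. T and NK cell genes were negative for 8 of 11, with a median of -0.43 (camera adjusted p = 9.53e-05; adjusted p = 0.549 with an estimated correlation). Of these, 0 were called over all genes tested and 2 adjusted over the list alone, Cd3d with a log2 change of -0.80 and Thy1 with -0.64. Of 20 genes of stem and multipotent progenitor cells, 18 were negative, with a median of -0.19 (camera adjusted p = 0.00171; adjusted p = 0.549 with an estimated correlation). The 1 called gene, also the 1 that passed adjusted over the list alone, was Slamf1, which was higher. Erythroid genes (median -0.06, camera adjusted p = 0.507) and megakaryocyte genes (median -0.14, camera adjusted p = 0.127) did not pass with all arrays. Their medians changed sign with single arrays left out. The erythroid median was 0.039 without C57B/L6 replicate 1, 0.024 without B.D(Chr5) replicate 1 and 0.011 without B.D(Chr5) replicate 3, and the megakaryocyte median was 0.017 without the last of these. The erythroid list passed, lower in B.D(Chr5), without C57B/L6 replicate 3 (adjusted p = 0.0053) or B.D(Chr5) replicate 2 (0.0016). The megakaryocyte list passed, also lower, without B.D(Chr5) replicate 1 (0.0075) or 2 (0.0188).

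Among the process lists, that of immediate early and stress genes was lower in B.D(Chr5) as a group with the preset correlation and not with an estimated one. Of 14 genes, 12 were negative, with a median of -0.75 (camera adjusted p = 9.07e-07; adjusted p = 0.440 with an estimated correlation). The median was -0.39 without B.D(Chr5) replicate 2. Of these genes, 0 were called over all genes tested and 3 adjusted over the list alone. The heat shock protein gene Hspa1b had signals of 4504 ± 3172 in C57B/L6 and 793 ± 664 in B.D(Chr5) (SD, n = 3 each). Its C57B/L6 arrays read 2380, 8150.3 and 2983. The transcription factor gene Egr1 had 939.7 ± 255 and 483 ± 62.8 (SD, n = 3 each). Interferon response genes were positive for 13 of 17, with a median of 0.07 (camera adjusted p = 0.0315; adjusted p = 0.569 with an estimated correlation) and 0 called either over all genes tested or adjusted over the list alone. The median was 0.013 without B.D(Chr5) replicate 3. Irf7 had a log2 change of 0.45. The lists for DNA replication (median -0.01, camera adjusted p = 0.778), mitosis (0.04, 0.127, and 0.0456 without C57B/L6 replicate 2), p53 targets (0.03, 0.318), DNA double-strand break repair (0.02, 0.507) and homing and adhesion (0.0020, 0.820) did not pass. For TGF-beta signalling, which did not pass either (camera adjusted p = 0.890), the median of -0.0025 and the mean of 0.0027 differed in sign. No direction held for these 6 lists, whose medians changed sign with single arrays left out. They ran from -0.036 to 0.013 for DNA replication, from -4e-04 to 0.061 for mitosis, from -0.025 to 0.069 for p53 targets, from -0.028 to 0.049 for repair, from -0.071 to 0.061 for homing and adhesion and from -0.018 to 0.062 for TGF-beta signalling. The 15 measured haematopoietic genes of chromosome 5 did not pass as a group (median 0.04, camera adjusted p = 0.318). The median was 0.0083, -0.045 and 0.15 without C57B/L6 replicates 1, 2 and 3, and 0.044, 0.066 and 0.017 without B.D(Chr5) replicates 1, 2 and 3. Of these genes, 0 passed over all genes tested or adjusted over the list alone. Prom1, the gene of the surface marker CD133, had a log2 change of 0.91 with an SE of 0.29. Of the background check genes, 3 were measured and 0 passed, with log2 changes of 0.11 for Myo5a, -0.42 for Klrd1 and 0.10 for Nnt.

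In all, 11 of the 20 lists passed with the preset correlation, 8 higher and 3 lower, and 0 passed with an estimated correlation, where 1 list, plasma cell genes, had an unadjusted p under 0.05. Some calls depended on single arrays. The B lymphoid list did not pass without C57B/L6 replicate 1 (adjusted p = 0.194) or B.D(Chr5) replicate 3 (0.841), and the T and NK cell list did not without B.D(Chr5) replicate 2 (0.102). The monocyte and dendritic cell list did not pass without C57B/L6 replicate 1 (0.664), B.D(Chr5) replicate 1 (0.124) or B.D(Chr5) replicate 3 (0.921). It also did not pass with no filter on signal (0.0565) or with the mean over a gene's probe sets (0.0671). The interferon response list did not pass without C57B/L6 replicate 1 (0.901) or B.D(Chr5) replicate 3 (0.825), nor with chromosome 5 genes left out (0.0547), with no filter on signal (0.0594) or without the arrays of highest 18S signal (0.285). Medians moved by over 1.5 times when 1 array was left out in these lists too. The B lymphoid median was 0.19 and 0.011 without C57B/L6 replicate 1 and B.D(Chr5) replicate 3, and 0.52 and 0.55 without B.D(Chr5) replicates 1 and 2. The T and NK cell median was -0.66 without C57B/L6 replicate 1. The monocyte and dendritic cell median was -0.014, 0.051, 0.31 and 0.026 without C57B/L6 replicate 1 and B.D(Chr5) replicates 1, 2 and 3. The interferon response median was 0.024 and 0.14 without C57B/L6 replicates 1 and 3, and 0.16, 0.15 and 0.013 without B.D(Chr5) replicates 1, 2 and 3.

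**Figure D3:**
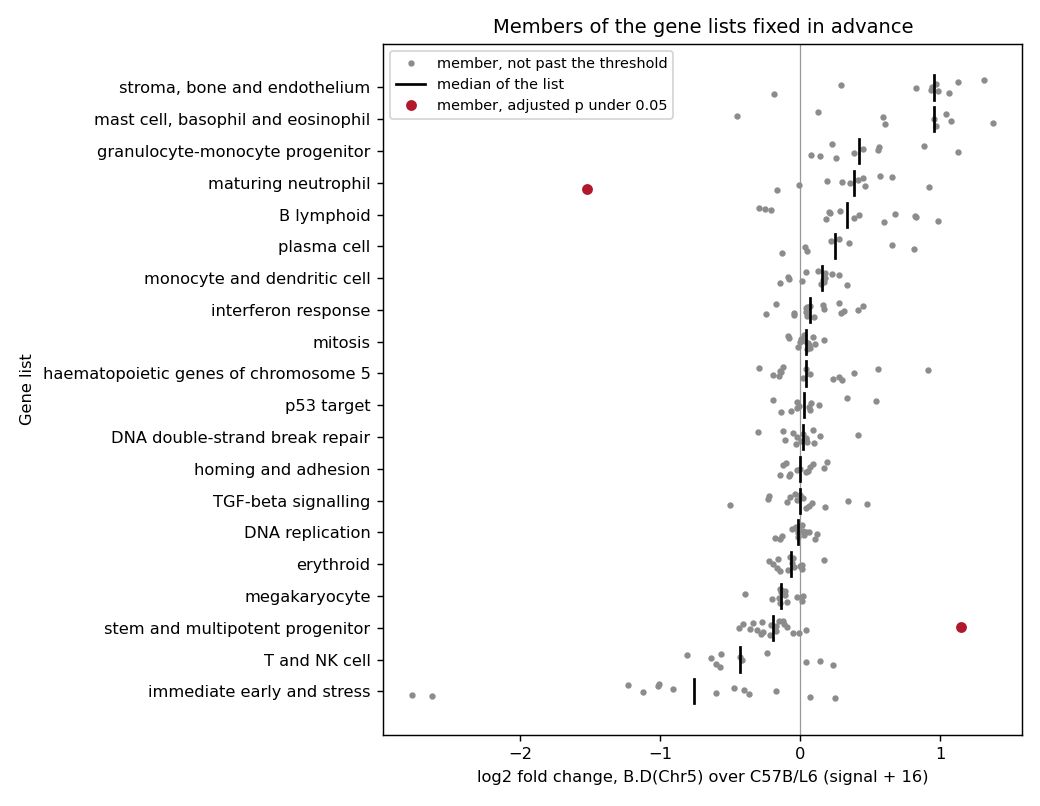
Log2 fold change of B.D(Chr5) over C57B/L6 for each measured gene of the 20 tested lists, 1 line per list, with points for genes, larger points for called genes and a bar at the median. All 10 granulocyte-monocyte progenitor genes lie above 0, and 12 of the 14 immediate early and stress genes lie below 0.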

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

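Leaving out the array with the highest 18S signal of each strain and all tests on chromosomes 1 and 3 were chosen after the data were seen. Of the alternatives to 41 called probe sets, the counts were 21 for a stricter filter on signal, 25 for eBayes without trend and 27 with the replicate number as a block, and leaving out 1 array gave 21 (without B.D(Chr5) replicate 1) to 73 (without B.D(Chr5) replicate 2). Leaving out probe sets whose names end in _x_at gave 29, all of them among the 41. Whether samples of the same number share anything but the number is not known. Their deviations from the strain means had correlations of -0.11, -0.20 and 0.20, against -0.16 to 0.30 for samples of different numbers. With 3 arrays per strain these deviations depend on each other, so the correlations cannot settle the matter. Higher and lower calls split 22 to 19 as reported, 16 to 15 with no filter on signal, 9 to 12 with the stricter filter, 11 to 14 without trend 16 to 11 with the block and 53 to 20 without B.D(Chr5) replicate 2. The stretch of chromosome 5 grew to 216 genes with no filter on signal (permutation p = 0.093), was 138 genes without trend (p = 0.103) and 132 with the block (p = 0.335), and ran from 131 to 293 with 1 array left out. It could not be computed with the stricter filter, which left 1 call. Chromosome 5 held 11.8% of the genes at an unadjusted p under 0.01 (Fisher exact p = 0.00568), 24 genes of which 20 lay within 255 (permutation p = 1e-04), and 12.5% to 18.2% of the called genes with 1 array left out. Chromosome 1 held 12% without the arrays of highest 18S signal (Fisher exact p = 0.165) and 9.26% to 27.3% with 1 array left out. The lists past the threshold went from 11 to 0 with an estimated correlation. The mean log2 change of the monocyte and dendritic cell list ran from -0.065 without C57B/L6 replicate 1 to 0.28 without B.D(Chr5) replicate 2. The megakaryocyte list passed with the block (adjusted p = 0.0422) and without the arrays of highest 18S signal (0.0339), as did mitosis in the latter (0.0434). No named called gene changed direction in any alternative run on it, and the cause of the other changes was not tested. Changes in probe sets near the bacterial controls are limited by signal, which the filter on dim probe sets removed below a mean of 66.7.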

Other observations

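The tests of placement along chromosomes 1 and 3, of second probe sets, of the correlation and the direction of cell type lists and of plasma cell genes were chosen only after the results were seen. Without B.D(Chr5) replicate 2, the array with the highest 18S signal, 39 probe sets passed the threshold that had not passed with all arrays, 36 of them higher in B.D(Chr5) and 11 of them of genes on the fixed lists. The genes named here were chosen after their values were seen. The basophil protease gene Mcpt8 had a log2 change of 1.67 without that array and 1.04 with all arrays, and Ms4a3 of granulocyte-monocyte progenitors had 1.52 and 1.12. Hp, which encodes the haemoglobin-binding plasma protein haptoglobin, had 1.32 and 1.01, and Alas1, the first enzyme of haem synthesis outside red cells, had 1.02 and 0.72. None of these 4 genes passed with all 6 arrays.

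A called probe set without a gene symbol had a signal of 79.4 ± 15.3 in C57B/L6 and 2049 ± 529 in B.D(Chr5) (SD, n = 3 each), a log2 change of 4.42 with an SE of 0.20.

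Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave 41 called probe sets, and the highest of the other 9 gave 0 in limma. At an unadjusted p under 0.05 the other splits had 258 to 2097 probe sets, several of them above the 1069 of the real one. For the gene lists, 2 of the 10 splits gave as many as the real 11, the highest of the others being 11 and their lowest 1. The splits are too few for a share under 0.05.

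The first pattern is the crowding of called genes on chromosomes 1 and 3, where random placement along the chromosome gave a stretch as short with a permutation p of 1e-04 for chromosome 1 and 1e-04 for chromosome 3, the smallest possible. On chromosome 1 the placements count the similar, neighbouring p200 genes as independent calls. Without the arrays of highest 18S signal, 9 of the 16 called genes still passed, but how close together they lay was not tested. Chromosome 3 then held 8 of 25 called genes (Fisher exact p = 1.40e-05) and chromosome 1 held 3 (Fisher exact p = 0.165). These arrays as the whole cause are thus argued against for the share on chromosome 3 and stay open for the share on chromosome 1. They were C57B/L6 replicate 1 and B.D(Chr5) replicate 2. On the other arrays Slamf1 read 364 and 282 in C57B/L6 against 650 and 596 in B.D(Chr5). Cd84 read 970 and 677 against 398 and 397, and Pex19 read 261 and 275 against 93.9 and 91.4. Ifi209, Mndal and Ifi202b also kept their directions. For these 6 genes, selected with all arrays in, the values argue against these arrays as the whole cause. Another candidate is the lower share of probe sets above the bacterial controls in B.D(Chr5) (65.6% against 70.4%). Array-wide quality acts without regard to position, though, and so would not crowd the calls (the same permutation p of 1e-04). Strain variants under the probes of a single probe set as the whole cause are argued against for the 10 genes with another tested probe set, as a group. Those other probe sets had a median log2 change of 0.65 in the called direction, against -0.03 to 0.08 for random genes. The called probe sets of these genes had a larger median size of 1.54. The other probe set of Slc30a7 went the opposite way, and those of Ifi209, Rwdd3 and Alg14 moved by at most 0.16. Variants that affect several probe sets of a gene alike were not covered by this check, nor were the called genes of chromosome 5. For the 6 genes with 1 tested probe set, probe variants cannot be told apart from a change in expression because nothing else reads these genes. A candidate explanation, as a hypothesis without a genotype to test it, is that B.D(Chr5) carries DNA of another strain in parts of chromosomes 1 and 3 as well as 5.

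The second pattern is the movement of cell type lists. Different mixes of cell types in the samples could give the median estimated correlation of 0.69 within the 11 cell type lists, against 0.09 in the 9 others. The ranges overlapped, from -0.04 (plasma cells) to 0.80 in the first and up to 0.46 in the second. The correlation was estimated after the strain difference was removed, so it describes variation between arrays of 1 strain. Whether mixes differed between the strains cannot be read from it. A single array as the whole cause was not excluded. At the fewest, 7 of the 9 cell type lists passed when 1 array was left out. With the same preset correlation, though, splits that mix the strains also passed 1 to 11 of the 20 lists, so this count cannot decide it. A lower share of 1 main cell type, which would raise the others alike, would need 1 sign in 6 lists of distinct cell types, whose medians were -0.43 for T and NK cells, -0.14 for megakaryocytes and -0.06 for erythroid cells against 0.96 for stroma, 0.38 for neutrophils and 0.34 for B lymphoid cells, the erythroid median being 0.039, 0.024 and 0.011 without C57B/L6 replicate 1, B.D(Chr5) replicate 1 and B.D(Chr5) replicate 3, and the megakaryocyte median 0.017 without the last. It cannot be told apart, since 1 of the 6 lists passed in the rarer direction and the mean of the 5 others less that of T and NK cells, centred over the arrays, was -0.29 ± 0.48 in C57B/L6 and 0.29 ± 0.41 in B.D(Chr5) (SD, n = 3 each; two-sided exact permutation p = 0.2). An effect of strain on the makeup of the marrow stays open as well and was not separated from differences in how completely each sample was depleted.

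The third pattern is the higher signal of immunoglobulin light chain genes. More antibody-secreting cells in the B.D(Chr5) samples could be neither shown nor excluded. The mean log2 change of the 8 plasma cell genes, 0.28, lay at percentile 99.88 among 10000 random lists matched on signal, but the list was already known to be higher, Ighm had -0.13, Prdm1 0.04 and Derl3 0.05, and the estimated correlation of -0.04 showed no joint variation of its members. Among the most abundant of these transcripts, the Igha probe set of smallest p, chosen after its values were seen, had 11172 ± 817 in C57B/L6 and 21136 ± 4633 in B.D(Chr5) (limma adjusted p = 0.0589), and Jchain had 11833 ± 339 and 14610 ± 3471 (SD, n = 3 each), neither past the threshold. The samples were depleted of cells bearing lineage markers, and which markers were used is not given in the sources used here. Strain differences in the variable genes themselves stay open and were not tested.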
